A study of Homo sapiens with 2 samples.

How the data were processed

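Total RNA from LM3 cells with Kindlin-2 shRNA or control shRNA was labelled with Cy3, per the labels' protocols, and each group has 1 single-colour Agilent array. The number of cultures behind each RNA sample is not given in the sources used here. The deposited scanner tables hold fluorescence intensity on a linear scale, which Agilent Feature Extraction 11.0.1.1 had corrected for background and spatial trend but not normalized between arrays, per the file headers. Both arrays come from 1 scan, per the file headers, so scan and group are not confounded. The scanner tables also carry flags of 0 or 1 per spot for outliers, saturation and signal well above background, set by the same software, per the file headers. A deposited series table holds log2 values. Its columns follow the log2 signal of their own arrays with r of 0.999 and 0.997, and both have a median of 6.29 and quartiles of 3.70 and 9.23, which shows that the authors quantile-normalized them and did not centre genes. How the authors treated their lowest values is not given in the sources used here.

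Each array held 44495 spots, of which 43118 were for genes, from 34127 probes, 999 of them with 10 spots. The flagged outlier spots, 297 on the Kindlin-2 shRNA array and 262 on the control array, were left out, and the remaining spots of a probe were averaged on the log2 scale. The main values are the log2 of the processed signal minus the array's 75th percentile over probes, which was 585 units on the Kindlin-2 shRNA array and 621 on the control array. A probe counted as well above background where at least 0.5 of its kept spots were flagged so. Differences are Kindlin-2 shRNA minus control shRNA.

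The scanner tables used here give transcript accessions in place of gene symbols. Accessions were matched without versions to the RefSeq gene table of assembly GRCh38.p14, used for names and for gene order only. Of 34120 probes with values on both arrays, 25767 were named by 1 symbol, giving 19737 symbols, and 8353 stayed unnamed and were left out of gene results. No coordinates are given, because the array's annotation uses another assembly. A gene's value is the mean over its probes well above background on at least 1 array. A gene not well above background on 1 array has a bound, the brighter array's level against the higher of the dim array's lowest detected signal and the probe's own signal.

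With 1 array per group there was no test, no p-value and no spread between replicates. Technical error was taken from replicate spots and from the scanner software's error estimate. The median SD of a difference between single spots was 0.07 (log2) for bright probes and 0.16 for dim detected probes, and the median SD between probes of a gene was 0.13 over 3402 genes. The r between the arrays was 0.994 across genes, which are not independent replicates. Spots within 2 rows and columns of the named genes' spots had a median shift of 0.01 (SE 0.01) in the genes' direction over 854 neighbouring spots.

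The genes named were fixed by rule before the data were examined. They are FERMT2, and the 14 highest and 14 lowest log2 differences among genes with an ordinary symbol (no locus, clone, transcript or open reading frame names) that pass these conditions. All used probes are well above background on both arrays and differ in the same direction, none is saturated on both, and the brighter array's signal is at or above the median of its detected probes. To these come the 4 largest bounds each way, up to 4 members of each list with the largest absolute difference, and FERMT1 and FERMT3. FERMT2 enters both by name and among the 14 lowest. The 40 gene lists were fixed at the same time. Some genes that the rule chose, and 1 of the lists, are not reported here. A list's median was set against 10000 random lists matched in 20 bins of mean expression, and it stands apart at or below percentile 2.5 or at or above 97.5.

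The steps were tested on simulated array pairs with the spot noise of these arrays, 20 pairs with 200 genes given known differences. Among bright genes 100% of those planted at log2 differences of -2, -1.5, 1.5 or 2 were recovered as 2-fold. Among all genes 85.3% were recovered at -2, 83.0% at -1.5, 96.4% at 1.5 and 99.3% at 2. Of 200 lists without a planted effect 8 lay outside the middle 95%, with noise drawn independently for each probe. The first form of the simulation set its detection limit too low and was corrected to match the detected share of the arrays.

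Alternatives were a 75th percentile over probes detected on both arrays, median scaling, quantile normalization, loess between the arrays, the authors' log2 values, probes detected on both arrays only, no filter on dim probes, the brightest probe of each gene, outlier spots kept, a 1.5-fold threshold, agreement of probes in direction, and random lists not matched on expression. Normexp background correction with an offset of 50, followed by quantile normalization, was run on median pixel intensities, because the mean intensities named in the plan are not among the columns used here. That form, the measured difference in place of a bound, and a limit to genes above median brightness were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.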

Results

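Gene expression was measured in LM3 cells, a human hepatocellular carcinoma line, after lentiviral delivery of a short hairpin RNA (shRNA) against Kindlin-2 or of a control shRNA. Kindlin-2, encoded by FERMT2, is an adaptor protein that binds the cytoplasmic tails of integrin beta subunits at focal adhesions. Infected cells were placed under 2 ug/ml puromycin 72 h after infection to select stable lines. RNA from each line was hybridised to 1 single-colour Agilent array, so each group holds 1 array, and the number of arrays limits the precision. No difference given here has a replicate check, and no test between the groups was made. On the Kindlin-2 shRNA array 71.4% of the gene-probe spots were well above background, against 77.7% on the control array, and no spot was saturated. A total of 16007 named genes were well above background on at least 1 array, of which 14820 were so on both, 1131 on the control array alone and 56 on the Kindlin-2 shRNA array alone.

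The labels were first checked against the targeted gene. FERMT2 was 4.28-fold lower on the Kindlin-2 shRNA array, at 23.4% of the control level, a log2 difference of -2.10 with an SD of 0.29 between its 2 probes. This was the lowest difference of all genes well above background on both arrays. Probe A_33_P3344477, designed on the transcript NM_001134999, read 4082 units on the Kindlin-2 shRNA array and 16104 on the control array, a log2 difference of -1.90. Probe A_33_P3344482, designed on NM_001135000, read 339 and 1769 units, a log2 difference of -2.30. The scanner software's own error for either probe's difference came to 0.20 on the log2 scale. Of the other kindlin genes, FERMT1 (Kindlin-1) gave 763 units against 673 with its detected probe, a log2 difference of 0.27 with a scanner error of 0.20, and its other probe was not well above background on either array. FERMT3 (Kindlin-3, the kindlin of blood cells) was not well above background on the Kindlin-2 shRNA array, with signals of 14.2 and 16.7 units.

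The study's title asks how Kindlin-2 acts on invasion and metastasis of liver cancer, and the comparison of all genes addresses what differed between the lines. Of the brighter genes chosen by the rule and detected on both arrays, the furthest above the control was TSPAN8, a cell-surface tetraspanin. TSPAN8 was 15.4-fold higher on the Kindlin-2 shRNA array (log2 difference 3.95, 1829 against 126 units). NKD2, a negative regulator of Wnt signalling that binds Dishevelled, was 7.83-fold higher (2.97), EPS8, an actin-capping and bundling protein, 5.79-fold higher (2.53), and the orphan nuclear receptor NR2F1 4.93-fold higher (2.30). Among the brighter genes chosen by the rule and detected on both arrays, the lowest after FERMT2 were H19, an imprinted long noncoding RNA, at 4.08-fold lower (-2.03), and FBN2, the microfibril protein fibrillin-2, at 2.97-fold lower (-1.57). The scanner error of each of these differences lay between 0.20 and 0.21 on the log2 scale, and each of these 6 genes had 1 probe.

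**Figure D1:**
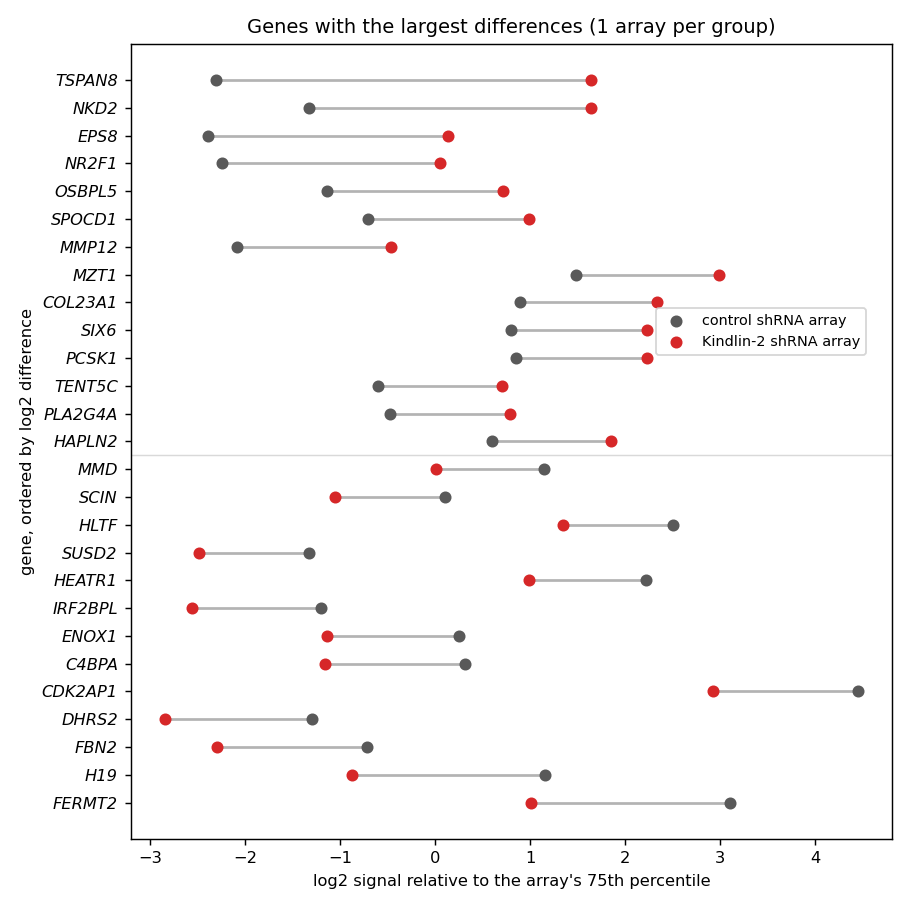
Levels of the genes furthest higher and furthest lower on the Kindlin-2 shRNA array that the rule for named genes chose and that are reported here; the x axis is the log2 signal relative to the array's 75th percentile, grey points are the control shRNA array, red points the Kindlin-2 shRNA array, and the line joins the 2 levels of a gene. TSPAN8 has the longest line of the higher genes (log2 difference 3.95) and FERMT2 of the lower genes (-2.10).

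Some genes of secreted or membrane proteins were present on both sides of the named genes, grouped here by description and not by a fixed list. The metalloelastase MMP12 was 3.08-fold higher (log2 difference 1.62), the transmembrane collagen COL23A1 2.72-fold higher (1.44), the proprotein convertase PCSK1 2.59-fold higher (1.37) and the hyaluronan link protein HAPLN2 2.39-fold higher (1.25). On the lower side stood C4BPA, a chain of the complement inhibitor C4b-binding protein, at -1.47 and the membrane protein SUSD2 at -1.16. The SUSD2 value was 0.03 when probes not well above background were kept, so its direction rests on the detected probe.

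Among other genes, SPOCD1 was 3.24-fold higher (1.69), MZT1, a component of the gamma-tubulin complex, 2.84-fold higher (1.51), the homeobox factor SIX6 2.70-fold higher (1.43), the poly(A) polymerase TENT5C 2.47-fold higher (1.31) and PLA2G4A, the cytosolic phospholipase A2, 2.40-fold higher (1.26). The lipid transfer protein OSBPL5 averaged 1.86, but its 2 probes disagreed, with 0.48 and 3.24. Other lower genes were the dehydrogenase DHRS2 (-1.55), the CDK2-associated protein CDK2AP1 (-1.53), ENOX1 (-1.38), IRF2BPL (-1.36), the ribosome biogenesis factor HEATR1 (-1.24), the helicase-like factor HLTF (-1.16), the actin-severing protein SCIN (-1.16) and MMD (-1.14). CDK2AP1 read 13566 units on the control array and 4439 units on the Kindlin-2 shRNA array.

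For genes not well above background on 1 array, the fold was taken against the higher of that array's lowest detected signal and the probe's own signal. Where the lowest detected signal was the higher, the fold is a lower bound on the signals as read. Spot error and a background difference between the arrays are not allowed for in it. Where the probe's own signal was the higher, the fold is the measured ratio, and the true fold can be smaller. FAM240A was at least 5.56-fold higher on the Kindlin-2 shRNA array, with a spot error of 0.74 on the log2 scale. The glutamate receptor GRM3 (6.98-fold), the apolipoprotein APOA2 (5.40-fold) and CFAP206 (4.88-fold) were higher there by the measured ratio. Their control signals were 12.2, 16.2 and 12.4 units, with spot errors of 0.50, 0.46 and 0.55 on the log2 scale. On the control array SERTAD4BP was at least 8.35-fold higher than on the Kindlin-2 shRNA array and SHISA9 at least 7.91-fold. The potassium channel gene KCNJ9 was at least 5.30-fold and the insulin-like gene INSL4 at least 5.25-fold higher there. The spot errors of SERTAD4BP, SHISA9, KCNJ9 and INSL4 were 0.64, 0.62, 0.69 and 0.54 on the log2 scale.

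Over all 16007 genes, 119 were at least 2-fold higher and 127 at least 2-fold lower on the Kindlin-2 shRNA array, 34 and 52 of them by a bound. At least 4-fold differences were 11 higher and 9 lower, and 92.9% of genes were less than 1.5-fold apart. Most of the 2-fold differences rested on 1 probe, 108 of the higher and 104 of the lower genes. In simulated pairs with no true difference, spot noise alone gave a median of 93 genes at least 2-fold higher (highest 108) and 38.5 at least 2-fold lower (highest 48). The simulated pairs held no background offset, while the negative controls of the real arrays differed by -2.77 scaled signal units. The simulated counts therefore cannot show whether the 127 lower genes exceed what such an offset gives. Among the 8692 brighter genes, 31 were at least 2-fold higher and 24 at least 2-fold lower, against at most 0 and 1 in the simulated pairs. The 14 highest and 14 lowest genes chosen by the rule come from these brighter genes. Genes named as list members had no such condition, and many are dim, among them SPP1, ADAM19, CXCL11, TRIM22, CLDN1 and APOA1 with spot errors of 0.44 to 0.58 on the log2 scale. Members given as bounds had spot errors of up to 0.85 (AXIN2).

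**Figure D2:**
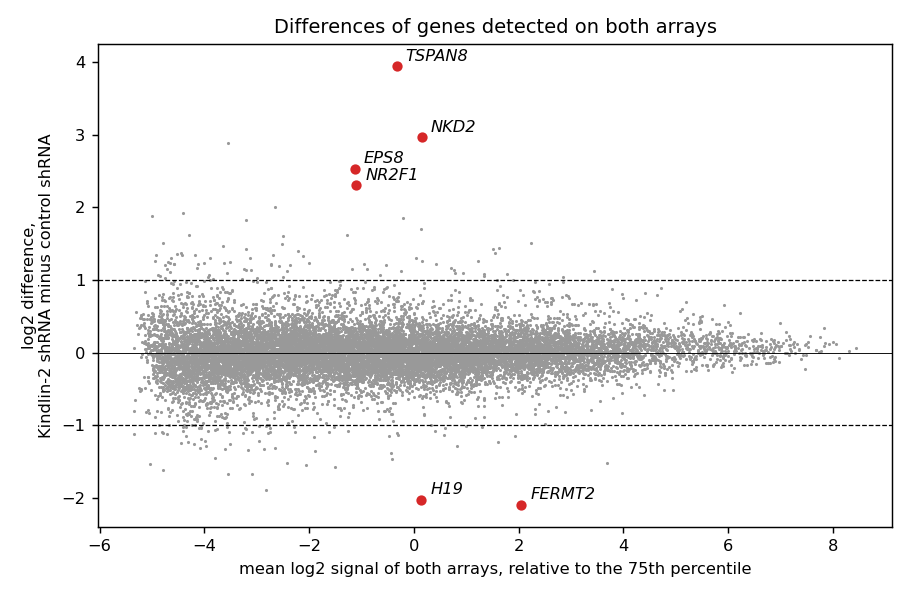
Log2 difference (y axis, Kindlin-2 shRNA minus control shRNA) against the mean log2 signal of both arrays relative to the 75th percentile (x axis) for the 14820 genes well above background on both arrays, 1 point per gene; dashed lines mark a 2-fold difference. FERMT2 (-2.10) lies lowest. Among the brighter genes chosen by the rule, H19 (-2.03) is the next lowest, and TSPAN8 (3.95) and NKD2 (2.97) are highest.

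Gene lists fixed before the data were examined were described by the median log2 difference of their detected members and its percentile among 10000 random lists of the same size and expression. Of 40 lists, 5 lay outside the middle 95%, where chance gives 2 if genes differ independently. Members of a list can differ together and some lists share members, so more can lie outside by chance. Percentiles describe these 2 arrays and are not tests of the shRNA. Cholangiocyte markers, genes of bile duct cells, were higher on the Kindlin-2 shRNA array, with 8 of 10 members above 0 and a median of 0.22 at percentile 99.5. Of the 10 members 2 were at least 1.5-fold higher, SPP1 (osteopontin) by 1.34 on the log2 scale, with a spot error of 0.49, and CLDN4 by 0.71. KRT19 was 0.28 higher, with a spot error of 0.18. Antigen presentation genes had 15 of 20 members above 0 and a median of 0.16 at percentile 99.4, with none 1.5-fold apart. TAP2 averaged 0.47, with probes at 0.07 and 0.86, the probes of CIITA disagreed (-0.02 and 0.88), and HLA-DMA was lower (-0.45). With the brightest probe of each gene in place of the mean over probes, the antigen presentation list lay at percentile 84.4, inside the middle 95%.

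The lists of cytosolic ribosomal proteins, the unfolded protein and amino acid stress response, and G2/M and mitosis lay on the lower side by small amounts. Cytosolic ribosomal protein genes had a median of -0.07, below all 10000 random lists, whose middle 95% spanned 0.01 to 0.12, and 36 of 49 members were below 0. The median was -0.13 after loess, -0.13 under quantile normalization and -0.04 with the brightest probe of each gene. RPS16 (-0.22) was lower and RPS12 (0.28) higher. RPL15 averaged -0.31, with probes at -0.56 and -0.06, and the probes of RPS23 disagreed (-0.57 and 0.06). The stress response list had a median of -0.09 at percentile 0.13, with 22 of 35 members below 0. VLDLR (-1.03), STC2 (-0.51) and the asparagine synthetase gene ASNS (-0.45) were lower, and SESN2 (1.03) higher. The G2/M and mitosis list had a median of -0.09 at percentile 0.43, with 26 of 38 members below 0 and none 1.5-fold apart, including PLK4 (-0.52), KIF11 (-0.39), MKI67 (-0.28) and CKS2 (0.39). Against random lists not matched on expression these 3 lists lay at percentiles 11.9, 7.60 and 6.70, inside the middle 95%.

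**Figure D3:**
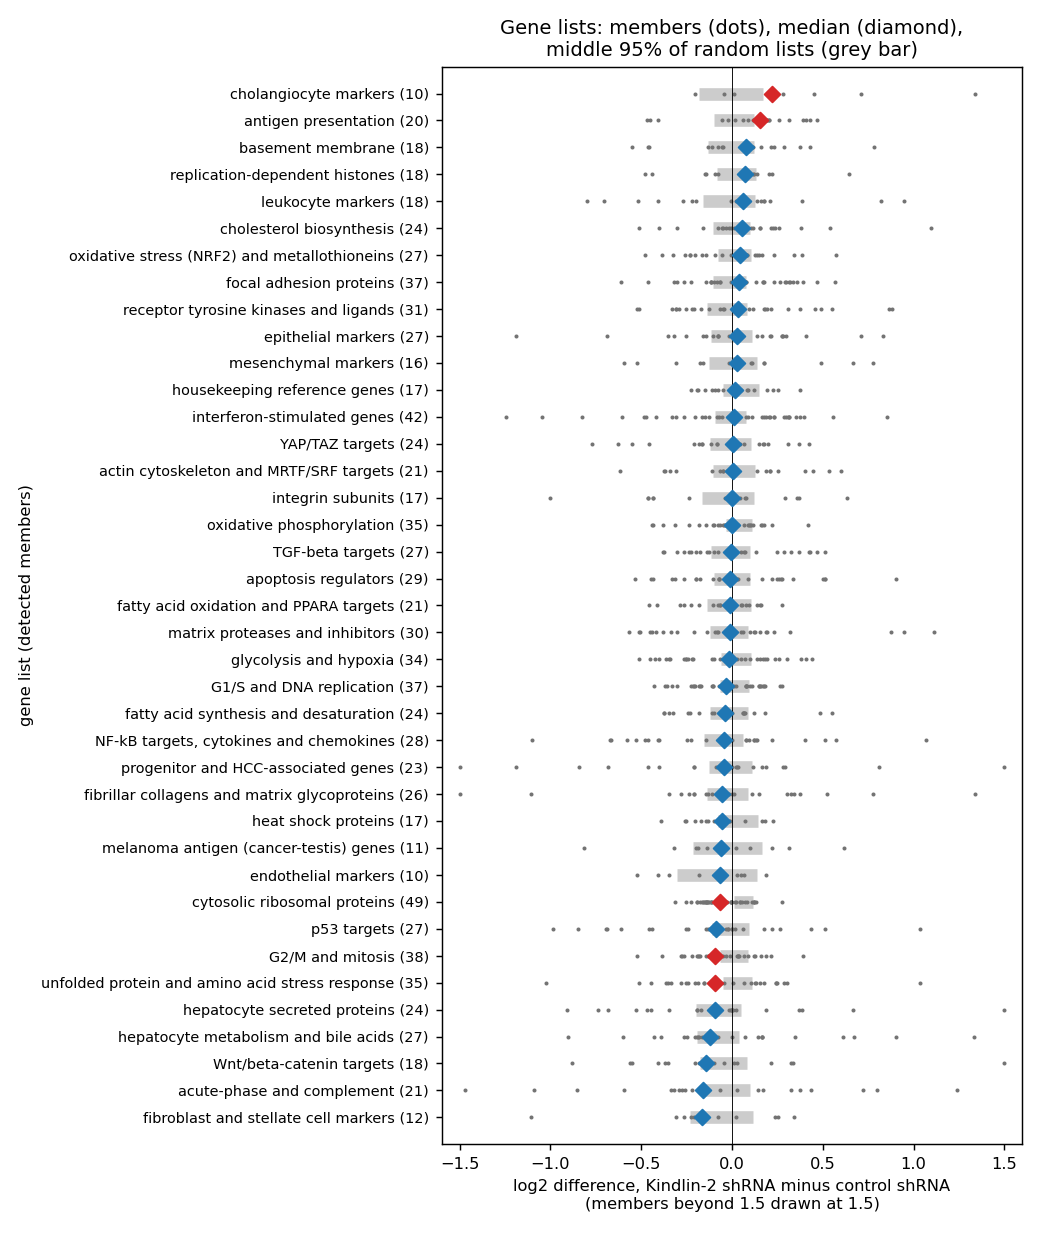
Log2 differences (x axis, Kindlin-2 shRNA minus control shRNA) of the detected members of each gene list reported here (y axis, number of detected members in brackets); dots are genes, diamonds are list medians, red where the median lies outside the middle 95% of random lists, and grey bars span that middle 95%. The 5 red diamonds are the cholangiocyte marker and antigen presentation lists on the right (0.22 and 0.16) and the ribosomal protein, G2/M and stress response lists on the left (-0.07, -0.09 and -0.09).

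The adhesion machinery in which Kindlin-2 works showed no shared shift. Of 17 detected integrin subunits 15 were less than 1.5-fold apart, and the list's median was 0.00 at percentile 64.9. The collagen-binding subunit ITGA1 was lower (-1.0), as were ITGB1 (-0.46) and ITGA6 (-0.46), and ITGB4, the partner of ITGA6 in hemidesmosomes, was higher (0.63). Focal adhesion proteins were less than 1.5-fold apart for 36 of 37 genes (median 0.04, percentile 87.1), with NEDD9 (-0.61) and RSU1 (-0.46) lower and VASP (0.57) and SRC (0.47) higher. Actin cytoskeleton and MRTF/SRF targets lay at percentile 41.2, with ACTG2 at -0.62 and EGR1 at 0.60.

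Matrix genes held larger single differences in both directions. Fibrillar collagens and matrix glycoproteins had 22 of 26 members less than 1.5-fold apart (percentile 26.9), with FBN2 at -1.57, the proteoglycan DCN (decorin) at -1.11, SPP1 at 1.34 and fibronectin, FN1, at 0.78. Matrix proteases and inhibitors had 3 of 30 members at least 1.5-fold higher and none that much lower (percentile 52.1). These were ADAM19 (1.11), MMP2 (0.88) and MMP7 (0.95), the last measured against a control signal not well above background. The basement membrane list lay at percentile 90.2, with the laminin chains LAMA1 at 0.78 and LAMC1 at -0.46.

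Markers of epithelial and mesenchymal state gave no single direction. The epithelial list lay at percentile 70.6, with CLDN1 (0.83) and CLDN4 (0.71) higher, CLDN7 lower (-0.69), and EPCAM lower by a bound of -1.19. The mesenchymal list lay at percentile 62.2, with FN1 (0.78) and GREM1 (0.67) higher and the transcription factors SNAI2 (-0.59) and ZEB2 (-0.53) lower. YAP/TAZ targets had 22 of 24 members less than 1.5-fold apart (percentile 56.6), the exceptions being IGFBP3 (-0.77) and FOXF2 (-0.63). All 27 TGF-beta targets were less than 1.5-fold apart (percentile 50.8), CDKN1A (0.51) being furthest. Wnt/beta-catenin targets had a median of -0.14 at percentile 6.69 (-0.06 with the authors' values and -0.07 with probes detected on both arrays only). NKD2 was higher (2.97). AXIN2 was lower by a bound of -0.88, with a spot error of 0.85 on the log2 scale. ZNRF3 averaged -0.56, with probes at -0.96 and -0.16.

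Liver genes also went both ways. Progenitor and liver cancer-associated genes included TSPAN8 (3.95), H19 (-2.03) and PEG10 (-0.84), with 17 of 23 members less than 1.5-fold apart and the median at percentile 24.1. Among hepatocyte secreted proteins (percentile 32.2) APOA1 was lower (-0.91), as was ceruloplasmin, CP (-0.68). APOA2 was higher (2.43), measured against a control signal not well above background. Hepatocyte metabolism and bile acid genes had a median of -0.12 at percentile 20.3, but of 0.02 at percentile 91.3 under quantile normalization, with the bile salt and drug transporter SLCO1B1 at -0.90 and the tryptophan dioxygenase TDO2 at 1.33, both bounds. Acute-phase and complement genes had a median of -0.16 at percentile 2.53, just inside the middle 95%. It lay outside in 4 of 14 settings, at percentile 0.85 after loess, 1.53 without a filter on dim probes, 1.61 against unmatched random lists and 0.54 among brighter genes. With probes detected on both arrays only, or the brightest probe of each gene, its median was -0.02 at percentiles 42.0 and 42.3. Their members C4BPA (-1.47), C4BPB (-1.09) and SAA4 (-0.85) were lower and FGL1 higher (1.24).

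Metabolic lists, the G1/S list and the p53 targets lay inside the middle 95%. Cholesterol biosynthesis lay at percentile 86.9, with MVD at 0.54 and HMGCS1 at -0.40. Fatty acid synthesis and desaturation lay at percentile 29.6, with ELOVL6 at 0.55 and SCD at -0.38. Fatty acid oxidation and PPARA targets lay at percentile 50.3, with PPARGC1A at -0.29 and CREB3L3 at 0.28. Glycolysis and hypoxia genes lay at percentile 18, with LDHA at -0.51, HK2 at -0.45 and ADM at 0.44. Oxidative phosphorylation genes lay at percentile 13.9, with the ATP synthase genes ATP5F1A and ATP5F1B at -0.44 each and COX5A at 0.42. The G1/S and DNA replication list lay at percentile 11.7, with RFC3 at -0.43 and MCM4 at -0.36. The p53 targets had a median of -0.09 at percentile 5.37 (-0.05 with normexp), with 5 of 27 at least 1.5-fold lower, among them TNFRSF10B (-0.98), TIGAR (-0.85) and RRM2B (-0.69), and SESN2 higher (1.03).

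Immune signalling genes differed singly. Of 42 interferon-stimulated genes 37 were less than 1.5-fold apart (percentile 62.5, or 98.7 among the 29 brighter members), while TRIM22 (-1.24), IFI44L (-1.04) and IFITM1 (-0.83) were lower and ISG20 (0.85) higher. Of 28 NF-kB targets, cytokines and chemokines 24 were less than 1.5-fold apart (percentile 51.3). The chemokine CCL2 was lower (-1.10) and CXCL11 higher (1.07), with a spot error of 0.32 and 0.44 on the log2 scale. Markers of other cell types gave percentiles of 84.6 for leukocytes, 53.2 for endothelial cells and 9.51 for fibroblasts and stellate cells, all inside the middle 95%. Housekeeping reference genes had a median of 0.02 at percentile 23.5 (-0.04 under quantile normalization), and all 17 were less than 1.5-fold apart.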

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

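The normexp correction, the measured difference in place of a bound and the limit to brighter genes were chosen after the results were seen. FERMT2 was -1.98 with normexp and -1.90 with the brightest probe, which is 1 of its 2 probes. Genes at least 2-fold higher, 119, and lower, 127, became 24 and 16 with normexp on spot medians followed by quantile normalization, 229 and 675 without a filter on dim probes, 502 and 633 at 1.5-fold, and 31 and 24 among brighter genes. The lower count was 77 with the authors' values, 64 with probes detected on both arrays only and 365 with the measured difference in place of the bound. Quantile normalization gave 145 higher and 88 lower and loess 139 and 99, so which direction has more genes depends on the normalization. Of the higher genes 118 were shared under quantile normalization, and of the lower genes 87. The number of lists outside the middle 95% was 3 when random lists were not matched on expression. SUSD2 was 0.0302 without the filter on dim probes, where dim probes enter its mean. For the other moved values the cause was not tested. Of 342 alternative values of the 35 genes named for the largest differences or bounds, FERMT2 left out, 330 stayed at least 2-fold the same way. Genes named only as list members are not among these. The count was in part fixed in advance, since all of the 35 genes except OSBPL5 used 1 probe. For those detected on both arrays, the brightest-probe and both-arrays settings could not change the value. Of 517 alternative list medians 467 moved by less than the SD of random list medians and 50 by more, with none of the called lists reversed. Dim signals limit the counts, since genes near background differ 2-fold from spot noise. No paired analysis was possible because each group has 1 array and no test was made.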

Other observations

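The tests of dim genes, of a difference between the RNA samples, and the follow-up tests of neighbouring genes (1 gene per name stem, bright genes) were chosen after the results were seen. Further gene lists lay inside the middle 95% of random lists. Receptor tyrosine kinases and ligands lay at percentile 86.9, with the receptor FGFR1 at 0.88, the EGFR ligand AREG (amphiregulin) at 0.86 and EPHA2 at 0.55. Of 29 apoptosis regulators 28 were less than 1.5-fold apart (percentile 42.3). The exception was BIK, a BH3-only protein, at 0.90, and APAF1, the core of the apoptosome, stood at -0.54. Heat shock protein genes had 13 of 17 members below 0 and lay at percentile 5.32, with the co-chaperone BAG3 at -0.39, HSPA8 at -0.26 and HSP90AA1 at 0.23. Oxidative stress (NRF2) and metallothionein genes lay at percentile 73.1, with HMOX1 at 0.39. Replication-dependent histones lay at percentile 77.7, with H1-4 at 0.64 and H1-2 at -0.44. The melanoma antigen (cancer-testis) list lay at percentile 34.4, with MAGEC2 at 0.62 and MAGEB1 at -0.81 by its bound.

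Members of the other cell type lists had single differences as well. Among leukocyte markers GNLY was at 0.95 with a spot error of 0.54, and ITGAM at 0.82. Among endothelial markers PECAM1 was at -0.41, and among fibroblast and stellate cell markers DCN was at -1.11 and COL1A1 at 0.34.

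Of the genes well above background on 1 array alone, 95.3% were detected on the control array. With 1 detection limit of 11.7 units for both arrays the share was 76.8%, and after the mean of the 153 negative control spots was also set to 0 on each array it was 54.2%, with 488 genes on the control array alone and 412 on the Kindlin-2 shRNA array alone. The negative controls, which match no transcript, averaged -7.11 units after background subtraction on the Kindlin-2 shRNA array and -4.77 on the control array. A candidate explanation of most of the excess is therefore a different background level and detection limit of the 2 arrays. A true loss of weakly expressed transcripts stays open, since the dimmest 1719 genes above the limit, chosen by the mean of both arrays, had a median difference of -0.0651 units with the offset removed, within the SE of 0.42. Earlier forms were dropped, because negative controls carry replaced values, quantile normalization fixes the share, or a choice by flags, which gave -1.18, favours the control array.

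For the lower cytosolic ribosomal protein transcripts, loess normalization left the list at percentile 0. That percentile is against lists of like expression, so removing an intensity-dependent trend between the arrays could hardly change it. Such a trend as the cause of the low median is argued against by the median itself, which went from -0.07 to -0.13 after loess. Chance in choosing the members is argued against only in part by the 37 cytosolic ribosomal protein genes left off the list. They lay at percentile 1.93 against lists of like expression, but their median was -0.01, against -0.02 over all genes. A loss of short transcripts in labelling would also lower 77 mitochondrial ribosomal protein genes, taken to be short, which lay at percentile 32.3. Their transcript lengths are not given here, so such a loss is argued against only in part. A difference between the 2 RNA samples unrelated to the shRNA cannot be told apart from an effect of the shRNA, because there is 1 array per group. A lower level of these transcripts with less Kindlin-2 may be biological only as a hypothesis. Its size is small, a median of -0.07, or -0.13 after loess and -0.04 with the brightest probe of each gene. Against random lists not matched on expression, run on the main values alone, the list lay at percentile 11.9.

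Genes that lie next to each other in the GRCh38.p14 gene order shared small shifts. In windows of 25 neighbouring genes the SD of the medians of loess-normalized differences was 1.26 times that of shuffled gene orders, where the highest of 1000 shuffles gave 1.09, and in windows of 100 genes it was 1.62 times. Similar neighbouring genes that share a probe signal or a regulator are argued against in part, since 1 gene per name stem and chromosome gave 1.26. Neighbouring genes of like brightness are argued against as the whole cause, since 8692 bright genes, less the median of their brightness bin, gave 1.22 (highest shuffle 1.11) and 1.61 in windows of 100 (highest shuffle 1.28). A hypothesis is that chromosome segments may differ between the 2 cell pools, but base composition of the probes and shared regulation of unlike neighbours were not tested.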
